A study of Mus with 6 samples.

How the data were processed

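RNA was measured on 6 one-colour Illumina mouse bead arrays, 3 from wild-type (WT) and 3 from Klf4-deficient mice. Each array held RNA of leukaemic cells sorted from mice with chronic myeloid leukaemia (CML) driven by the p210 form of BCR-ABL, 14 days after transplantation. The sort kept green fluorescent cells without lineage markers that carried Sca-1 and c-Kit, the LSK phenotype of stem and early progenitor cells, per the series' design text. Groups and replicate numbers were taken from the sample titles. The labels do not say that the 3 samples of a group came from separate mice, so p-values measure the spread between these samples, which may be technical.

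The deposited values are intensities on a linear scale, 1 per probe and array, with 45281 probes. Target preparation, scanning and image analysis were done by a service laboratory, per the labels' protocols, and BeadStudio was used, per the submitters' processing notes. Its version, the background method and the normalization method are not given in the sources used here. The values themselves ran from -31 to 37007.2, with 45.3% to 45.6% of each column at or below 0, so a background had been subtracted. The 6 columns held nearly the same sorted values, within 5% or 0.15 of each other at 95.4% of the ranks, so they had been put on one scale before deposit. Column medians were 1.6 to 1.7, lower quartiles -6.4 to -6.3 and upper quartiles 15.1 to 15.6. The medians are further apart than 5% only because they lie near 0, where the deposited resolution is 0.1, and the columns were treated as being on one scale. Such scaling makes the arrays equal in total brightness, so a sample with less RNA or fewer expressed genes cannot be told from the totals. All 6 value columns were used.

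No further normalization was applied. Values below 32 were set to 32 and the log2 was taken. A floored value says only that the probe was not above 32, and fold changes against it understate the difference. Where a group lay wholly at the floor, the fold is the mean log2 value of the other group against the floor and is written as "at least". Probes were named through the platform annotation, with symbols updated through their Entrez numbers in a RefSeq gene list. Of the probes, 34885 had 1 symbol, 18 had several and 10378 were not listed in that annotation. Several probes of a gene were represented by the probe with the highest mean. Probes with several symbols or none entered the test as themselves and were not named. Features whose mean was above the median of all probe means were tested. That median equalled the floor, so the filter kept the 13773 of 29453 features that exceeded 32 on at least 1 array, 10236 of them with a symbol. Between 7082 and 7214 probes per array, 15.6% to 15.9%, lay above 32. Probe sequences and genome positions were not used here.

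Klf4-deficient and WT arrays were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all features tested and a threshold of 0.05. Values were handled with the R package data.table (version 1.17.8). No replicate block was used. For Klf4, Dyrk2 and other genes given by value, each probe was also fitted with all probes of the array. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over all 26 lists, and beside it with camera at an estimated correlation and with fry. The lists, test, groups, alternatives and naming rule were fixed before the data were examined. The 16 pathway lists covered stem cell and self-renewal regulators, p53 targets, pro-apoptotic and anti-apoptotic genes, MYC targets with ribosome biogenesis, G1/S with DNA replication, G2/M with mitosis, cell cycle inhibitors with quiescence genes, the KLF family, DYRK and SIAH genes with regulators of MYC and p53 stability, STAT5 and RAS/MAPK feedback targets, type I interferon response, immediate early genes, heat shock with the unfolded protein response, glycolysis and oxidative phosphorylation. The 10 cell type lists covered neutrophil, monocyte and macrophage, erythroid, megakaryocyte, B cell and lymphoid progenitor, T and NK cell, mast cell and basophil, eosinophil, dendritic cell, and stroma and endothelium. Of their 556 genes, 512 had a named probe and 373 were tested.

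The naming rule took Klf4 and Dyrk2 and then 12 named genes in each direction. Called genes came first by fold change. Since no gene was called, the 12 were those with the smallest unadjusted p in that direction whose 3 Klf4-deficient arrays did not overlap the 3 WT arrays. For each list, called members or otherwise up to 2 members with the smallest p were eligible, and Myc, Trp53, Siah2, Cdkn1a, Cdkn1b, Cdkn1c, Gfi1, Kit, Ly6a and Cd34 were given by value where measured. Unnamed probes and predicted genes were passed over. Trp53 and Ly6a had 0 probes named in the annotation used here and were not analysed.

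The fitting step was tested on simulated data for the comparison of Klf4-deficient with WT, drawn from the means and spreads of the 13773 features with 3 arrays per group. Of 200 features changed 4-fold, 0 reached the threshold, although 135 had an unadjusted p under 0.05, and 4 unchanged features were called. Of 200 features changed 16-fold, 51% were called, with 14 unchanged features called. A simulated shift of 1 (log2) in the 29 tested oxidative phosphorylation genes gave a camera adjusted p of 1.29e-07, with 0 other lists called. Genes were drawn independently there, so sensitivity for correlated genes was not tested. In the data, the lowest camera adjusted p of a list was 0.17 at the preset correlation and 0.64 at an estimated one. In the simulation, changes of 4-fold in single genes were thus below what the test called, and the number of arrays limits the precision. Each simulated feature had the same spread in both groups, while the median SD in the data was 0.73 in WT and 0.33 in Klf4-deficient arrays. An unadjusted limma p under 0.05 was reached by 5.41% of the unchanged simulated features, against 298 of 13773 features in the data. The sensitivity in the data may therefore differ.

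Alternatives were a repeated quantile normalization, median centring, floors of 16 and 64, an offset of 16, eBayes with trend and robust options, a replicate block, leaving out each array, no filter, features above percentile 75 of probe means, the mean of a gene's probes, an ordinary t statistic, other thresholds, and other set tests. An offset of 32, array weights, and leaving out the WT replicate 3 array with features chosen over all 6 arrays (also with an offset of 32, on features chosen anew or on the same probes) were added after the data were seen. Apart from fits said to use features of all 6 arrays or the same probes, each alternative chose its features and probes anew. A list's mean can then rest on other members.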

Results

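Gene expression was measured in leukaemic LSK cells, the fraction enriched for leukaemia stem cells, from WT and Klf4-deficient CML mice. Klf4 encodes a zinc finger transcription factor, and the series title concerns the kinase DYRK2, apoptosis and self-renewal of these cells. There were 3 arrays per group, with 7082 to 7214 probes per array above an intensity of 32. Over the 13773 features tested, WT replicate 3 correlated with the other 5 arrays at Pearson r = 0.29 to 0.31 across features, which are not independent replicates. The other 5 arrays correlated with each other at 0.68 to 0.74, within groups (0.68 to 0.74) as well as between them (0.70 to 0.74). The first principal component, with 46.4% of the variance, separated WT replicate 3 from the rest. The median SD within a group was 0.73 (log2) in WT and 0.33 in Klf4-deficient arrays, and 58.7% of the tested values lay at the floor.

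**Figure D1:**
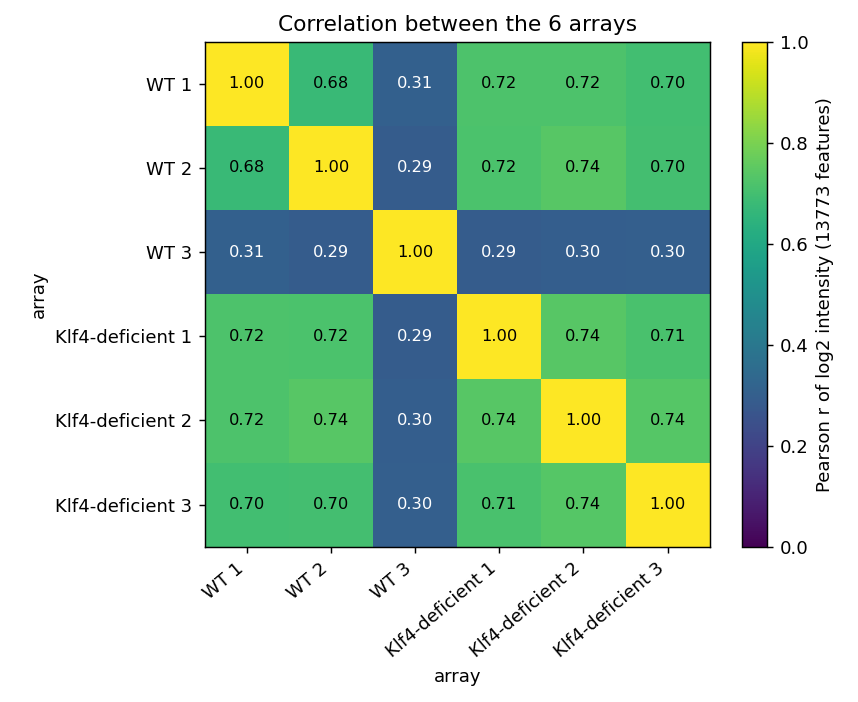
Pearson correlation of log2 intensity between each pair of the 6 arrays over 13773 features, as a colour scale from 0 to 1 with the value in each cell. WT replicate 3 lies at 0.29 to 0.31 with every other array, and the other 5 arrays lie at 0.68 to 0.74 with each other.

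The targeted gene and DYRK2 were examined first. Klf4 was near background in both groups. Of its 3 probes on 6 arrays, 1 value exceeded the floor, 51.9 in WT replicate 2 on probe ILMN_2999439, and on that probe the other WT arrays read -5.1 and -2.8 and the Klf4-deficient arrays 3.6, -1.9 and -2.2. With all Klf4-deficient arrays at the floor and 1 of 3 WT arrays above it, the Klf4 difference is only a limit. It was -0.23 ± 0.26 (log2, SE, n = 3 per group, limma adjusted p = 0.72 over the features tested). The array thus gave no check of the knockout labels, and the position of the probes relative to the deleted part was not analysed here. Dyrk2, a kinase that primes several proteins including MYC for degradation, read -1.2, 58.8 and 18.9 in WT and 33.4, 8.3 and 19.4 in Klf4-deficient arrays on its brighter probe, and stayed below the floor on all arrays on the other. The difference of -0.27 ± 0.31 (log2, SE, n = 3 per group) did not pass the test (limma adjusted p = 0.72 over the features tested). Its value turned to 0.05 with an offset of 16 in place of the floor and to 0.02 without WT replicate 2, whose value also carries the Klf4 difference, which became 0 without that array. A difference in Dyrk2 transcript was not detectable at this signal.

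The comparison of Klf4-deficient with WT cells asks which transcripts depend on Klf4 in the leukaemic stem cell fraction. The 12 named genes most separated upward included Alas2, which catalyses the first step of haem synthesis in erythroid cells, and Thy1, a surface glycoprotein of T cells and some progenitors. Alas2 was at least 4.58-fold higher in Klf4-deficient arrays (2.20 ± 0.23 log2, SE, n = 3 per group), with 172, 114.1 and 160.7 against 8.8, 26.1 and -15 in WT. Thy1 was at least 4.55-fold higher (2.19 ± 0.25), with 113, 187.2 and 146 against 24.4, 26 and -7. Fdx2, a mitochondrial ferredoxin of iron-sulfur cluster synthesis, was at least 5.03-fold higher, and Uhrf1bp1 at least 5.30-fold. Prkch, a protein kinase C isoform, was at least 6.63-fold higher, Plpbp, a pyridoxal phosphate binding protein, at least 3.84-fold, and Nfya, a subunit of the CCAAT-binding factor NF-Y, at least 3.10-fold. Ergic3 and Ergic2, proteins of the compartment between endoplasmic reticulum and Golgi, were 4.89-fold and 4.11-fold higher. Cggbp1 was 4.27-fold, Coro2a 4.76-fold and Fcf1 2.65-fold higher. All 12 had an adjusted p of 0.71 to 0.72 in limma, so none passed the test.

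The 12 named genes most separated downward included 2 of DNA synthesis. Tyms, thymidylate synthase, was 3.10-fold lower in Klf4-deficient arrays (-1.63 ± 0.25 log2, SE, n = 3 per group), with 68.9, 48.2 and 62.6 against 151.2, 200.2 and 204.6 in WT. Fen1, the flap endonuclease of lagging strand synthesis, was 2.99-fold lower (-1.58 ± 0.28). Ms4a3, a gene of granulocyte and monocyte progenitors, was 5.22-fold lower (-2.39 ± 0.47). Polr3g, a subunit of RNA polymerase III, was at least 8.72-fold lower, Shfl, an antiviral inhibitor of ribosomal frameshifting, at least 5.70-fold, and Gorasp2, a Golgi stacking protein, at least 3.83-fold. Kin was at least 3.74-fold and Lbh at least 2.63-fold lower. Grm6, a glutamate receptor, was 7.31-fold lower, Asnsd1 5.88-fold, Pla2g15, a lysosomal phospholipase, 5.66-fold, and Rbmxl1 2.48-fold. These 12 also had adjusted p-values of 0.71 to 0.72 and did not pass the test. Gorasp2 was the 1 named gene that leaving out 1 array moved by over 1.5 times, to -0.81 (log2) without WT replicate 2 and -1.08 without WT replicate 3, where another of its probes became the brightest. With the mean of a gene's probes, 13 of the 24 named genes moved by over 1.5 times, such as Tyms to -0.31, Ms4a3 to -0.60 and Plpbp to 0.49.

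Across the 13773 features, 0 were called by limma at an adjusted p under 0.05, and 0 under 0.1. The lowest adjusted p was 0.45, of the unnamed probe ILMN_2944601 (at least 4.65-fold higher in Klf4-deficient arrays, 2.22 ± 0.17 log2), singled out after its values were seen. An unadjusted p under 0.05 was reached by 298 features, 209 higher and 89 lower in Klf4-deficient arrays, where chance gives about 689. The ordinary t statistic called 1 feature, that same probe, with 193 at an unadjusted p under 0.05. The 2 groups did not overlap for 469 features, or 3.41%, where chance without ties gives 10%, and other splits gave 381 to 704 features. In both counts the real split ranked 8 from the top of the 10 splits. Without WT replicate 3, 0 features were again called and the split at an unadjusted p under 0.05 turned to 146 higher and 272 lower. Of the 24 named genes, 13 had further probes, of which 8 had the same sign, 7 the opposite sign and 7 lay at the floor. The opposite signs included a probe of Ms4a3 at 1.18, of Lbh at 0.81, of Ergic2 at -1.02 and 2 of Tyms at 0.47 and 0.84.

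**Figure D2:**
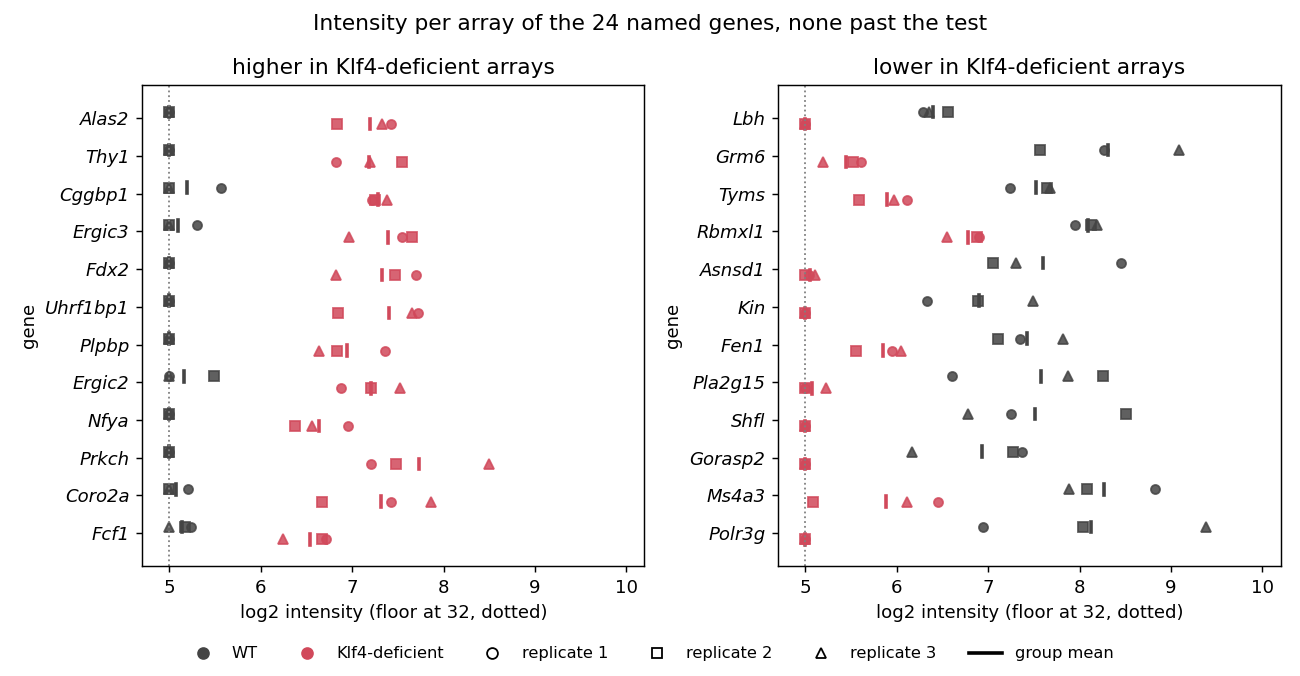
Log2 intensity of the 24 named genes on each array, WT in grey and Klf4-deficient in red, with a marker shape per replicate, a bar at each group mean and the floor of 32 as a dotted line. The groups do not overlap for any of these genes, which were chosen for that, 12 have 1 group wholly at the floor, and none passed the test (adjusted p 0.71 to 0.72).

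The gene groups nearest to the title of the series, apoptosis, p53, DYRK and self-renewal, were not called as sets. Of 17 tested pro-apoptotic genes, 8 were higher and 9 lower in Klf4-deficient arrays, with a mean difference of 0.08 (log2) and a median of -0.02 (camera adjusted p = 0.79), and the mean lay between -0.14 without WT replicate 1 and 0.25 without WT replicate 2. Cytochrome c, Cycs, differed by 1.62 ± 0.50 (SE), and its partner in the apoptosome, Apaf1, was at least 1.55-fold lower, with all Klf4-deficient arrays at the floor, both with an adjusted p of 0.72. Of 12 anti-apoptotic genes, 8 were higher (mean 0.27, adjusted p = 0.36), with Birc3 at least 2.71-fold higher (2 of 3 Klf4-deficient arrays above the floor, adjusted p = 0.72), and the mean turned to -0.16 without WT replicate 1. Of 26 p53 targets, 16 were higher (mean 0.19, adjusted p = 0.47), among them Pmaip1, which encodes NOXA, at least 3.47-fold higher (adjusted p = 0.72), while Apaf1 had the smallest p. That mean lay between -0.003 without Klf4-deficient replicate 1 and 0.36 without Klf4-deficient replicate 2. Of 17 DYRK, SIAH and MYC or p53 stability genes, 12 were higher (mean 0.23, adjusted p = 0.40), with the kinase Hipk2 at 2.95 ± 0.82 and the p53 inhibitor Mdm4 at -2.76 ± 1.29. That mean lay between -0.02 without Klf4-deficient replicate 3 and 0.55 without Klf4-deficient replicate 2. Siah2, a ubiquitin ligase, lay below the floor on all arrays. Myc differed by -0.35 ± 0.39 on its brighter probe and 0.14 ± 0.39 on the other. Of 25 stem cell and self-renewal regulators, 14 were higher (mean 0.22, adjusted p = 0.43), with the Polycomb gene Suz12 at 1.55 ± 0.62, and the mean lay between -0.01 without WT replicate 3 and 0.41 without WT replicate 1. Kit, a gene of the sort gate, read 11.5, 17.4 and 381.5 in WT and 118.1, 7.3 and 63.1 in Klf4-deficient arrays on its brightest probe. It was thus above the floor on 1 WT and 2 Klf4-deficient arrays, and highest in WT replicate 3. A second Kit probe was highest in WT replicate 2 (258.5), with -6.6 in WT replicate 3. The Kit difference on the brightest probe was -0.24 ± 1.30, with an SE from the fit over all probes, as for Myc. Cd34 was at least 1.11-fold and Gfi1 at least 1.35-fold higher (adjusted p = 0.75 and 0.72), each with all WT arrays at the floor and 1 of 3 Klf4-deficient arrays above it. No member of these lists was called, over all genes or adjusted over the list alone.

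Cell cycle lists were not called as sets. Of 24 G1/S and DNA replication genes, 13 were higher and 11 lower (mean 0.05, median 0.43, camera adjusted p = 0.96), and the mean lay between -0.27 without WT replicate 3 and 0.22 without WT replicate 1. Adjusted over the list alone, 2 members passed the threshold, Tyms (0.024) and Fen1 (0.025), both lower in Klf4-deficient arrays, against 0 over all genes. Their unadjusted limma p, 0.00099 and 0.0021, was 0.00032 and 0.0012 with a floor of 64 and 0.014 and 0.019 with an offset of 16. It was 0.18 and 0.19 with trend and robust eBayes, where neither could pass over the list. Of 21 G2/M and mitosis genes, 14 were higher (mean 0.003, adjusted p = 0.36), with means from -0.18 without WT replicate 1 to 0.14 without Klf4-deficient replicate 3. Of 15 cell cycle inhibitors and quiescence genes, 9 were higher (mean 0.36, adjusted p = 0.36), and the mean lay between 0.08 without WT replicate 3 and 0.68 without WT replicate 2. Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21, read 15.5, 84.2 and 131 in Klf4-deficient arrays against 10.4, 9.9 and 4.7 in WT. That difference was at least 2.21-fold with 2 of the 3 Klf4-deficient arrays above the floor, and did not pass the test (1.14 ± 0.55 log2, SE, limma adjusted p = 0.72). A second Cdkn1a probe read 28.6, 59.7 and 92.4 against -13.5, 1.7 and -6.9, and the last lay below the floor on all arrays. Cdkn1b differed by -0.82 ± 1.20, over all probes, and Cdkn1c was at least 1.10-fold higher, with 1 of 3 Klf4-deficient arrays above the floor (adjusted p = 0.76). Of 9 KLF family genes, 5 were higher (mean 0.61, adjusted p = 0.37), led by Klf6 at 2.53 ± 1.20. That mean was 1.12 without WT replicate 2, 1.09 with a floor of 64 (adjusted p = 0.14) and 1.48 above percentile 75 of probe means (adjusted p = 0.093), and 0.34 with an offset of 32, in a range of adjusted p from 0.093 to 0.92 over the alternatives. Of 28 MYC target and ribosome biogenesis genes, 16 were higher (mean 0.37, adjusted p = 0.37), and the mean lay between 0.22 without WT replicate 3 and 0.71 without WT replicate 1. Among them the mitochondrial chaperone Hspd1 was at 1.74 ± 0.77 and the serine hydroxymethyltransferase Shmt2 at least 1.89-fold lower (adjusted p = 0.72 for Shmt2).

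The lowest p-values among the lists were those of interferon and respiratory chain genes. Of 18 type I interferon response genes, 12 were higher in Klf4-deficient arrays and 6 lower, with a mean of 0.47 (camera unadjusted p = 0.0064, adjusted p = 0.17; adjusted p = 0.64 with an estimated correlation). The antiviral genes Rsad2 and Ifit2 differed by 2.48 ± 0.75 and 2.12 ± 0.72 (adjusted p = 0.72 each). The list reached an adjusted p of 0.029 without Klf4-deficient replicate 1 and 0.030 without Klf4-deficient replicate 3, in a range of 0.0021 to 0.46 over the alternatives, the highest without WT replicate 3, and its mean was 0.72 without Klf4-deficient replicate 3. A split that mixed the groups, WT replicates 1 and 3 with Klf4-deficient replicate 1 against the rest, gave this list a lower p. It was 0.0047 in camera (adjusted p = 0.12), and the remaining mixed splits gave unadjusted p of 0.023 to 0.76. Of 29 oxidative phosphorylation genes, 21 were higher (mean 0.46, adjusted p = 0.27), with the ATP synthase subunit Atp5b at 1.37 ± 0.56 and Cox5a at 1.95 ± 0.82, and the mean was 0.13 without WT replicate 3. Of 15 glycolysis genes, 10 were higher (mean 0.37, adjusted p = 0.37), with Pgam1 at 1.33 ± 0.71, and the mean lay between 0.07 without WT replicate 3 and 0.75 without WT replicate 2. Of 19 STAT5 and RAS/MAPK feedback targets, 11 were higher (mean 0.27, adjusted p = 0.36), with the cytokine Osm at 1.69 ± 0.52, and the mean was 0.002 without WT replicate 3. Of 12 immediate early genes, 5 were higher and 7 lower (mean 0.13, median -0.22, adjusted p = 0.50), with Egr1 at 1.58 ± 0.33 (adjusted over the list alone, 0.051), and the mean lay between 0.003 without Klf4-deficient replicate 3 and 0.43 without WT replicate 3. Of 20 heat shock and unfolded protein response genes, 11 were higher (mean 0.02, adjusted p = 0.74), with Xbp1 at 1.07 ± 0.46, and the mean lay between -0.20 without WT replicate 3 and 0.28 without WT replicate 1.

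Markers of other cell types, which the sort should have removed in part, were compared in the same way. Of 12 erythroid genes, 6 were higher and 6 lower (mean 0.49, camera adjusted p = 0.36), the mean was 0.83 above percentile 75 of probe means, and Alas2 was the 1 member past the threshold adjusted over the list alone (0.0020), against 0 over all genes. Of 9 T and NK cell genes, 5 were higher (mean 0.35, unadjusted p = 0.031, adjusted p = 0.27), with Thy1 the 1 member past the threshold adjusted over the list alone (0.0022), against 0 over all genes, and the mean was 0.66 without WT replicate 3. All WT arrays of Alas2 and Thy1 lay at the floor, so those groups had no spread. Their unadjusted limma p, 0.00017 and 0.00024, was 0.0017 and 0.0027 with a floor of 64 and 0.022 and 0.0067 with an offset of 16. It was 0.052 and 0.053 with trend and robust eBayes, where neither could pass over its list. Of 8 dendritic cell genes, 7 were lower (mean -0.55, adjusted p = 0.36), led by the class II gene H2-Ab1 at -3.38 ± 0.91, and the mean lay between -0.83 without WT replicate 3 and -0.33 without WT replicate 2. Of 7 monocyte and macrophage genes, 6 were lower (mean -0.34, adjusted p = 0.36), while Ctss, the member with the smallest p, was at least 2.15-fold higher (2 of 3 Klf4-deficient arrays above the floor, adjusted p = 0.72), and Lyz2 was at -1.04 ± 0.78. Of 6 B cell and lymphoid progenitor genes, 4 were lower (mean -0.30, adjusted p = 0.67). The monocyte mean was -0.62 without WT replicate 2 and the B cell mean -0.78 without Klf4-deficient replicate 2. These means became 0.11 and 0.10 without WT replicate 3, which held the highest Csf1r value of the 6 arrays, 274.3. Of 9 stroma and endothelium genes, 7 were lower (mean -0.36, adjusted p = 0.36), and the mean lay between -0.54 without WT replicate 1 and -0.23 without WT replicate 3. Of 14 neutrophil lineage genes, 8 were higher (mean 0.02, median 0.10, camera direction down, adjusted p = 0.96), with Mpo, myeloperoxidase, at -0.99 ± 0.58, and the mean was -0.03 without WT replicate 3, -0.17 without Klf4-deficient replicate 3 and 0.13 without Klf4-deficient replicate 1. Of 10 mast cell and basophil genes, 6 were higher (mean 0.25, adjusted p = 0.36), and the mean lay between -0.07 without WT replicate 3 and 0.48 without WT replicate 1. Of 3 eosinophil genes, 2 were higher (mean 0.39, adjusted p = 0.40), with the granule protein gene Prg2 at least 2.16-fold higher (adjusted p = 0.72). Of 7 megakaryocyte and platelet genes, 3 were higher (mean 0.20, median -0.01, adjusted p = 0.96), with means from -0.03 without WT replicate 1 to 0.69 without WT replicate 2.

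In total 0 of the 26 lists were called by camera, 3 had an unadjusted p under 0.05, and 0 were called with an estimated correlation (lowest adjusted p = 0.64) or by the directional fry test (0.37). The mixed fry test, which asks whether members change in either direction and compares with no other genes, called 3 lists, erythroid (adjusted p = 0.00091), G1/S and DNA replication (0.0038) and T and NK cell (0.0038), the lists with members past the threshold adjusted over the list alone. The mixed fry calls and the list-alone passes come from the main fit only. The single-gene p behind the latter changed with the floor and the eBayes options, as given above. Leaving out 1 array moved the means of 24 of the 26 lists by over 1.5 times or turned them. Features were chosen anew in each of these fits, 11269 without WT replicate 3 against 13773 with all arrays. Such a move can therefore come from other members as well as from other values.

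**Figure D3:**
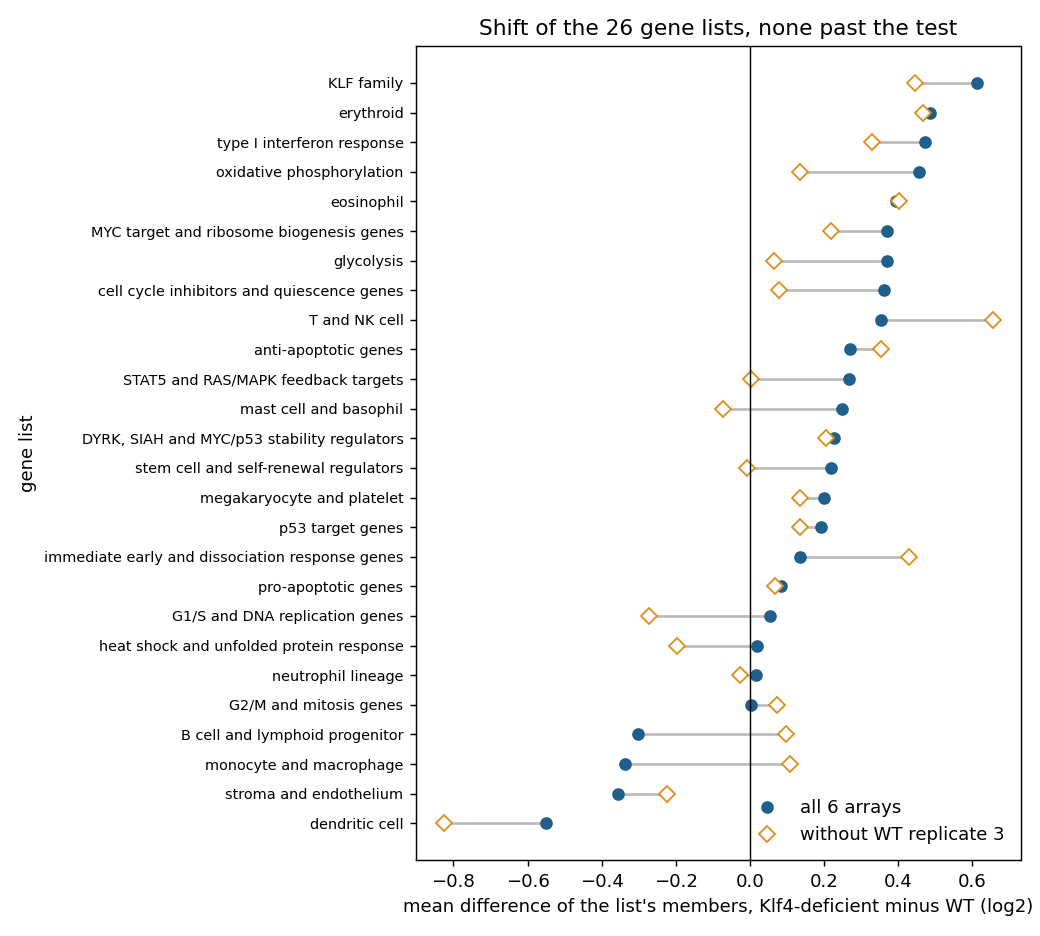
Mean log2 difference, Klf4-deficient minus WT, of the tested members of each of the 26 gene lists, with filled circles for all 6 arrays and open diamonds without WT replicate 3. None of the 26 lists passed the test, and the means of several lists, such as monocyte and macrophage (-0.34 and 0.11), lie on opposite sides of 0 with and without that array.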

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

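Array weights, the offset of 32 and fits without WT replicate 3 on features of all 6 arrays were added after the data were seen. Signal over background limits all results, since 58.7% of tested values lay at the floor. Of 432 values of the named genes under alternatives, 430 kept direction and side of the threshold. Choosing genes without overlap fixes direction on the same probe, so this is no test of stability. Sizes moved by over 1.5 times for 18 of 24 genes with a floor of 64 (Nfya to 0.63, Fcf1 to 0.54, Coro2a to 1.32). Alas2 went to 4.01 with an offset of 16. Gorasp2 passed under array weights (-2.31, adjusted p = 0.041, in a range of 0.041 to 0.91) but was smaller with a floor of 64 (-0.94) and, where another of its probes became the brightest, with a floor of 16 (-0.91), an offset of 16 (-0.71) or 32 (-0.57) and without WT replicate 2 (-0.81) or 3 (-1.08). Lbh turned to 0.46 with a floor of 64, where its other probe was brighter. The count of called features, 0, was 1 with no filter, 1 with the mean of a gene's probes and 1 with the ordinary t statistic, each time the unnamed probe ILMN_2944601. It was 3 with array weights (that probe, Gorasp2 and Spast, named after their values were seen) and 17 without WT replicate 3 with features chosen over 6 arrays, 0 of which were called with an offset of 32, on features chosen anew or on the same probes. It was 0 under the other alternatives, among them leaving out each array and thresholds of 0.1 or 1.5-fold. The number of features at an unadjusted p under 0.05, 298, ranged from 161 (trend and robust eBayes) to 718 (offset of 32 without WT replicate 3) and was 561 with an offset of 16, 506 with an offset of 32, 506 with array weights, 193 with the ordinary t statistic, 577 without WT replicate 1 and 670 without WT replicate 2. Median centring and a repeated quantile normalization moved values by 0 and at most 0.04 (log2), so both say little about stability.

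Replicate numbers were not taken to pair samples, since same-numbered samples deviated together at correlations of only 0.037, 0.048 and 0.047 across features. Between the groups, each sample's deviation from its group mean did correlate best with that of its own number, a hint from the data and not from the design. The other pairs lay at -0.037 to -0.0091, and the deviations of a group sum to 0, so the pairs are not independent. With replicate number as a block, 0 features and 0 lists were called, and 295 features had an unadjusted p under 0.05.

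The Klf4 difference was -0.57 with a floor of 16, -0.45 with an offset of 16, 0 with a floor of 64 and between -0.35 and 0 when each array was left out. The Dyrk2 difference was 0 with a floor of 64, 0.046 with an offset of 16, -0.024 with an offset of 32 and between -0.42 and 0.021 when each array was left out. The count of called lists, 0, was 14 with no filter, where flat features make up much of the comparison set by construction, 1 with the mean of a gene's probes (type I interferon response, adjusted p = 0.013, in a range of 0.0021 to 0.46) and between 0 and 1 when each array was left out. Of 464 list values, 414 kept their direction and side of the threshold, 17 newly passed it and 33 turned sign. Settings other than a left-out array moved 25 of the 26 means by over 1.5 times or turned them, such as stem cell genes to 0.47 with an offset of 16, p53 targets to 0.06 and anti-apoptotic genes to 0.07 with the mean of probes, and eosinophil genes to 0.67 with a floor of 16. With a floor of 64 the mean was -0.028 for G1/S, -0.19 for G2/M, -0.012 for anti-apoptotic, -0.074 for heat shock and -0.033 for neutrophil genes. Above percentile 75 of probe means it was -0.043 for G2/M and -0.00067 for neutrophil genes. With array weights it was 0.15 for B cell, -0.25 for G1/S, -0.0068 for STAT5 and RAS/MAPK, -0.24 for heat shock, -0.094 for mast cell, 0.012 for monocyte and -0.029 for neutrophil genes. When each array was left out, the mean ranged from -0.78 to 0.096 for B cell, -0.017 to 0.55 for DYRK and SIAH, -0.27 to 0.22 for G1/S, -0.18 to 0.14 for G2/M, -0.16 to 0.35 for anti-apoptotic, -0.20 to 0.28 for heat shock, -0.072 to 0.48 for mast cell, -0.030 to 0.69 for megakaryocyte, -0.62 to 0.11 for monocyte, -0.17 to 0.13 for neutrophil, -0.0029 to 0.36 for p53 target, -0.14 to 0.25 for pro-apoptotic and -0.0080 to 0.41 for stem cell genes. Features were chosen anew under these settings, so a mean's members can differ. The cause of these changes was not tested.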

Other observations

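Some transcripts were above the floor of 32 on all 6 arrays, irrespective of group. This rule includes WT replicate 3, where 45.4% to 46.9% of the probes above 100 on 4 other arrays were at or below the floor. The counts and rankings below therefore depend on that array. Of all 13773 features tested, 1085 were above the floor on all 6 arrays. Among cell type markers, the erythroid and the mast cell and basophil lists were the best represented for their size, with 5 of 12 and 4 of 10 tested genes above the floor on every array. Hdc, the histidine decarboxylase of histamine synthesis, read 1739.3 to 8245.9, Cpa3, a mast cell carboxypeptidase, 551.5 to 1435.6, Mcpt8, a basophil protease, 584.1 to 1510.2, and Tpsb2, a tryptase, 33.1 to 373. Of the erythroid genes, the anion exchanger Slc4a1 read 505.2 to 1341.7, Car2 364.3 to 1486.2 and the water channel Aqp1 253.7 to 5026.4. The myeloid granule gene Mpo read 1422.1 to 7153.2. Prf1, the perforin of cytotoxic cells, read 1706.1 to 6855.6 and Siglech, of plasmacytoid dendritic cells, 1167.1 to 4102.6. Mpo, Prf1 and Siglech were each the only member of their list above the floor on every array, so they do not stand for those lists. No monocyte and macrophage, stroma, eosinophil, megakaryocyte or B cell marker was above the floor on all 6 arrays (0 in each of these lists). The megakaryocyte genes Gp9 and Gp5 were above it on 2 WT and 3 Klf4-deficient arrays.

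Among the pathway lists, 8 of 29 oxidative phosphorylation, 7 of 20 heat shock, 6 of 28 MYC target and 6 of 24 G1/S genes were above the floor on every array. Npm1, a nucleolar chaperone, read 1097.5 to 4044.3, and Odc1, the ornithine decarboxylase of polyamine synthesis, 1090.9 to 2591.2. The chaperones Hsp90aa1 and Hspa8 read 1189 to 8015.4 and 860.6 to 2475.3. The replication helicase subunit Mcm6 read 392.3 to 1441.3 and Rrm2, of ribonucleotide reductase, 204.7 to 527.9. Of the stem cell regulators, Lmo2 was the 1 gene of 25 above the floor on every array, at 299.6 to 717.8. Others, such as Ctnnb1, Msi2, Gata2 and Hoxa7, were above it on 2 WT and 3 Klf4-deficient arrays.

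The tests of transcript loss, of a wrong label and of groups at the floor, and the count of splits by called features, were chosen after the results were seen, as was the comparison of marker lists with random lists. WT replicate 3 stood apart from the other 5 arrays, and a wrong label alone is argued against as the reason, since WT and Klf4-deficient arrays among the other 5 correlated at 0.696 or more, although correlation does not show which group WT replicate 3 belongs to. Loss of transcripts from scarce or degraded RNA was examined as another reason. In WT replicate 3, 45.4% to 46.9% of the probes above 100 on 4 other arrays were at or below the floor, against 1.13% to 2.78% in the other arrays. Of its own probes above 100, 32.9% were above the floor on no other array, against 6.50% to 8.30% in the others. On columns with nearly the same sorted values, a low correlation brings such shares whatever its cause. They therefore cannot tell loss of transcripts from other reasons. The deviations of 2 probes of a gene correlated across 280 genes at 0.357 (95% interval 0.25 to 0.46, and 0.36 in WT replicate 1), between the limits of 0.3 and 0.5 set for independent and shared deviation, so the test left this open. Cells of another type stay open too: the monocyte and macrophage list had the highest median, 1.40 (log2) above the other arrays, with Csf1r at 274.3, Lyz2 at 215.1 and Cd14 at 84.7, followed by stroma and endothelium at 1.23 and B cell at 0.85. The first 2 of these lists pass the limit of 1 set beforehand, but they lay at percentiles 93.8 and 86.3 of matched random lists. The B cell list lay at percentile 88.8 and the erythroid list, with a median of -0.17, at 93.7. The sort gate should remove cells of these types, and no other biological explanation was tested since the design gives none for 1 array.

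Leaving out WT replicate 3 while choosing features over all 6 arrays called 17 features, 16 of them lower in Klf4-deficient arrays. They included Gnaz (-2.74), Gorasp2 (-2.32), Spast (-2.38) and the apoptosome gene Apaf1 (-0.76), named after their values were seen, each but Spast a limit with 1 group at the floor. Of the 17, 82.4% had 1 group wholly at the floor, against 57.3% of all features. The latter share is taken over all 13773 features, among them 2693 that were constant over the 5 arrays and so showed no difference. An offset of 32 in place of the floor gave 0 calls, while features tested went from 13773 to 16871 and those at an unadjusted p under 0.05 from 398 to 718. On the same 13773 probes the offset again gave 0 calls, with 552 at an unadjusted p under 0.05, 16 of the 17 among them and all 17 in the same direction. The median size of the 17 differences was 2.23 (log2) with the floor and 2.13 with the offset, but their median residual SD went from 0.049 to 0.26 and the prior SD of the test from 0.036 to 0.49, so the calls ended through the spread and not the fold. The floor's lack of spread may thus account for the calls passing the threshold. The 17 were chosen on these same values, so their direction and size with the offset are no independent support for the differences. Whether these genes differ biologically was not tested.

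The 6 samples make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 0 features and the highest of the others 3. For gene lists the real split called 0 and the highest of the others 1. With a count of 0, all 10 splits give at least as many by construction, so these counts say nothing about chance. Features above the floor on all 3 arrays of 1 group and at the floor on all 3 of the other numbered 130 in the real split and up to 184 in another, with 8 of the 10 splits giving at least as many.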
